A study of Mus musculus with 24 samples.

How the data were processed

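RNA of sorted bone marrow cells from C57BL/6 mice was measured on 24 one-colour arrays. Per the labels' protocols, the mice received tamoxifen to delete Bap1 systemically, total RNA was extracted with a column kit, amplified by in vitro transcription with amino-allyl UTP and coupled to Cy5. The labels give a genotype, a sorted population and a mouse for each array. There were 4 groups: LSK cells (lineage-negative, Sca1-positive, Kit-positive, enriched for hematopoietic stem cells) and myeloid progenitors (lineage-negative, Sca1-negative, Kit-positive), each from mice labelled wild type (WT) and knockout (KO). Each group held 2 mice and each mouse 3 arrays, so that 8 mice gave all arrays, and no mouse gave both populations.

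The deposited values are log2 expression values processed by the authors, and the submitters' processing notes name limma without a version. The log scale and the between-array normalization were read from the values: they run from 5.66 to 15.93, and the sorted values of the 24 arrays differ by at most 0.0451 at any rank, as after quantile normalization. The scanner, the background correction and any filter on spots are not given in the sources used here. Arrays carry no count depth, and the number of mice, 2 per group, limits the precision.

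The table held 22439 probes. Gene names came from the platform's annotation, updated through a RefSeq gene table of the assembly GRCm38.p6, which was used for names only. By current symbol 18213 probes were matched and by synonym 2126, while 36 kept the array's own name and 2064 had no symbol. No probe listed several genes. The named probes covered 17741 genes, of which 2277 had several probes. A gene was represented by its brightest probe, the one with the highest mean over all arrays. Among the genes called in LSK cells, 115 had several probes, and in 29 of them another probe had the opposite sign, in 0 of them past the threshold. In 20 of the 115 another probe passed in the same direction. The same figures for myeloid progenitors were 60, 10, 0 and 20.

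The mouse was the replicate. Arrays of the same mouse were averaged, and the 8 mouse means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options), with all 4 groups in the fit sharing a spread with 4 residual degrees of freedom and a median prior of 6.91. P-values are two-sided limma p-values adjusted by Benjamini-Hochberg over all 22439 probes, with a threshold of 0.05. Contrasts were KO minus WT in LSK cells, KO minus WT in myeloid progenitors, the mean of these contrasts, their difference, and WT LSK cells minus WT myeloid progenitors. The 33 gene lists, the tests and the rule for naming genes were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and beside it with camera at an estimated correlation and with fry.

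Genes were named by this rule. For each KO minus WT comparison, Bap1 was named, with the 10 highest and 10 lowest log2 fold changes among genes past the threshold whose KO mice lay both on one side of both WT mice and whose brighter group lay above the median probe mean of 7.20. From each list that passed camera or had a member past the threshold, up to 4 members with the largest absolute change could be named. For the other contrasts the 5 highest and 5 lowest were named, for the difference with the brightness condition alone, and filled to 5 by unadjusted p where fewer passed. Genes of the sex-linked list served as a check of the mice. Genes named outside this rule are said to have been chosen after their values were seen.

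The fit was tested on simulated arrays built from the real means and spreads, in 20 draws with 200 of the 22439 probes changed in each. For the LSK contrast it recovered 30.0% of probes changed by 0.5 on the log2 scale, 72.2% of those changed by 1, 95.5% of those changed by 2 and 97.6% of those changed by 3, and 9.29% of its calls were false, above the nominal 5%. For the myeloid progenitor contrast 9.15% of calls were false, and for the average 8.43%. A second simulation with 1000 changed probes, added after the first had been seen, gave 5.04%, 5.08% and 4.95% in that order. The share of false calls was thus above nominal where few probes changed. The difference between the contrasts and the comparison of WT populations were not simulated. Of 600 simulated lists without a shift over 17741 genes, camera called 0 for the LSK contrast and 1 for the myeloid progenitor contrast. The simulated genes varied independently of each other, whereas the interferon response list, for example, had an estimated correlation of 0.398. The simulation therefore cannot show how often camera at the preset correlation calls unshifted lists of correlated genes.

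Alternatives were all arrays with the mouse as a random block, the same with the array number as a further block, arrays as independent samples, fits with the compared groups alone, repeated quantile normalization, median centring, filters at the 25th and 50th percentile of probe means, eBayes without trend and robust options, an adjusted p under 0.1, a fold change of at least 1.5, probes averaged per gene, and each mouse left out in turn. With a mouse left out, the remaining mouse of its group was assumed to vary like the other groups. For the fits with a random block, lists were tested with the pre-ranked form of camera. A fit without the 2 mice that showed a Kdm5d signal and a fit with that signal as a covariate were added after seeing the data.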

Results

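The series compared the transcriptomes of blood-forming cells from mice with and without BAP1, a nuclear deubiquitinase that acts on histone H2A. LSK cells, the bone marrow fraction enriched for hematopoietic stem cells, and myeloid progenitors were each measured in 2 WT-labelled and 2 KO-labelled mice, with 3 arrays per mouse. Arrays of the same mouse correlated with a median r of 0.994 across probes, arrays of different mice of a group with 0.987, WT with KO arrays of a population with 0.978, and arrays of different populations with 0.959. In a principal component analysis of the 8 mice, the first component (53.9% of the variance) separated the populations and the second (21.7%) the genotypes.

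Bap1 itself was not lower in the KO-labelled mice. Its only probe (mMC004004) read 11.55 and 11.45 on the log2 scale in the WT-labelled LSK mice against 11.96 and 11.84 in the KO-labelled ones, a change of 0.40 ± 0.18 (SE, limma adjusted p = 0.321). In myeloid progenitors it read 11.54 and 11.59 against 11.67 and 11.85, a change of 0.20 ± 0.18 (adjusted p = 0.843). Where the probe lies relative to the deleted part of the gene is not given in the sources used here, so this probe does not check the labels, and KO and WT stand below for the genotype on the label. The Y-linked gene Kdm5d read 7.88 in 1 WT LSK mouse (mouse 1) and 8.15 in 1 WT myeloid progenitor mouse (mouse 5), against 5.93 to 6.03 in the other 6 mice. The X-linked transcript Xist read 7.37 and 7.28 in these mice, 7.51 in the other WT myeloid progenitor mouse (mouse 6) and 7.80 to 7.87 in the other 5 mice. Both mice with this signal were WT, and values without them are given beside the counts.

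**Figure D1:**
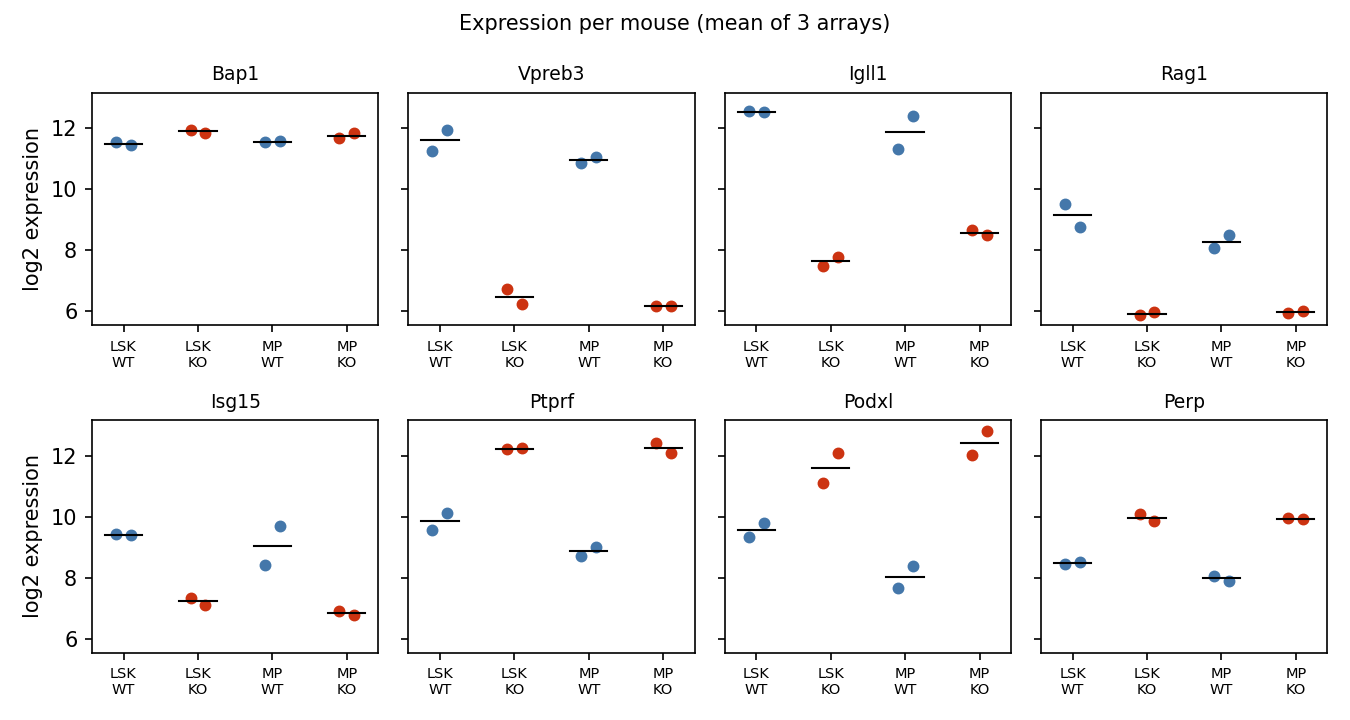
Log2 expression of 8 genes in each mouse (points, means of 3 arrays) with group means (lines), for WT (blue) and KO (red) LSK cells and myeloid progenitors (MP). Bap1 lies between 11.45 and 11.96 in all mice, while Vpreb3 lies between 10.86 and 11.95 in the 4 WT mice and between 6.17 and 6.74 in the 4 KO mice.

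The largest decreases in KO LSK cells were in genes of early B-cell development. Vpreb3, Igll1 and Vpreb1, which encode the surrogate light chain of the pre-B cell receptor or a partner of it, changed by -5.13 ± 0.26, -4.91 ± 0.31 (30.1-fold) and -4.19 ± 0.37 (18.2-fold) on the log2 scale (SE, n = 2 mice per group). For each gene said here to have risen or fallen in a population, both KO mice lay on the same side of both WT mice. Rag1, which cuts DNA for antigen receptor rearrangement, fell by 3.22 ± 0.24, and the endothelial and stem cell sialomucin Emcn fell by 3.01 ± 0.26. Of the basophil proteases, Prss34 fell by 2.79 ± 0.19 while Mcpt8 rose by 2.42 ± 0.18.

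Some of the named genes lay near the low end of the arrays in their dimmer group, where a log2 change is best read as a minimum and no fold is given. The 25th percentile of the arrays was 6.15 to 6.18 and their lowest value 5.66. Among the genes past the threshold whose change with the genotype is given in the Results for the population in question or on average, the mean lay under 6.5, a level chosen after the values were seen, for Vpreb3, Rag1 and Ebf1 in KO mice and Tcp11x2 in WT mice of both populations. The same held for Apol11b and Spib in KO LSK cells, Trnp1 in WT LSK cells, and Erfe and Phlda3 in WT myeloid progenitors.

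The largest increase in KO LSK cells was in the tight junction gene Cldn5, by 3.60 ± 0.24 (12.1-fold, adjusted p = 7.56e-05). Tcp11x2 (1700008I05RIK on the array) rose by 2.99 ± 0.21, the lipoprotein receptor Lsr by 2.66 ± 0.26, Trnp1 by 2.54 ± 0.28, the heparan sulfate endosulfatase Sulf2 by 2.42 ± 0.20, the receptor phosphatase Ptprf by 2.39 ± 0.24, the sulfotransferase Sult1a1 by 2.36 ± 0.33, the macrophage marker Cd68 by 2.26 ± 0.27 and the matrix protein Emilin2 by 2.24 ± 0.28. Tnfrsf17 (-2.84), Emp1 (-2.76), Apol11b (-2.66) and Tspan6 (-2.64) completed the 10 largest decreases. Of these 20 genes, Apol11b alone lost its call in some fits without 1 mouse (without mouse 1, 2, 3, 4, 7 or 8, at -2.73 to -2.60, adjusted p up to 0.181).

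In all, limma called 824 of 17741 genes in LSK cells, 309 higher and 515 lower in KO. Of these, 166 and 264 differed by at least 2-fold. Without mouse 1 the count was 428, without mouse 4 it was 969 with more genes higher (504) than lower (465), and without both mice with a Kdm5d signal it was 330 (94 higher, 236 lower).

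Of the 33 gene lists, 7 passed camera in LSK cells, against 12 without mouse 1 and 13 without mouse 2. In the B cell list 8 of 15 measured members fell and 0 rose (12 fell when adjusted over the list alone), with a median change of -0.66 (adjusted p = 0.0683 with an estimated correlation). Ebf1, a transcription factor that specifies the B lineage, fell by 2.04 ± 0.14. In the lymphoid priming list 7 of 14 fell (10 adjusted over the list alone; median -0.79, adjusted p = 0.346 with an estimated correlation), among them the interleukin-7 receptor gene Il7r, by 2.11 ± 0.24. In the interferon response list 9 of 38 fell and 0 rose (18 fell adjusted over the list alone; median -0.55, adjusted p = 0.813 with an estimated correlation). The ubiquitin-like Isg15 fell by 2.19 ± 0.35, and lost its call without any 1 of the 4 LSK mice (-2.29 to -2.08). Irgm2 fell by 1.58 ± 0.26, with -1.34 and adjusted p = 0.0533 without mouse 1.

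The dendritic cell list also shifted down in KO LSK cells, with 4 of 16 members lower and 1 higher (9 and 1 adjusted over the list alone; median -0.52), including the transcription factor Spib (-1.49 ± 0.20). It did not pass without mouse 4 (median -0.25, adjusted p = 0.165) or among probes above the 50th percentile (-0.69, adjusted p = 0.150). In the monocyte and macrophage list 1 of 21 members rose, Cd68, and 1 fell, Mpeg1 (2 and 5 adjusted over the list alone; median -0.39). Mpeg1 (-1.18 ± 0.23) lost its call without mouse 2 or 3 (adjusted p up to 0.102), and the list without mouse 3 (median -0.24, adjusted p = 0.134) or mouse 4 (-0.37, adjusted p = 0.161). The list also did not pass with the Kdm5d signal as a covariate (-0.24, adjusted p = 0.0732) or among probes above the 25th (-0.44, adjusted p = 0.0674) or 50th percentile (-0.53, adjusted p = 0.206). The immediate early and heat shock list had 0 of 26 members past the threshold (0 adjusted over the list alone), with a median of -0.37. Its members Fosb (-1.45 ± 1.13) and Jun (-1.42 ± 0.68) did not pass, and without mouse 1 its median was 0.00267 (adjusted p = 0.825), without both mice with a Kdm5d signal the same (adjusted p = 0.803), with that signal as a covariate -0.11 (adjusted p = 0.265) and among probes above the 50th percentile -0.40 (adjusted p = 0.0593). The amino acid synthesis and one-carbon list shifted up with 0 of 15 members past the threshold (0 adjusted over the list alone; median 0.40), and did not pass without mouse 4 (0.26, adjusted p = 0.165). Asns (1.59 ± 0.49, adjusted p = 0.162) and Mthfd2 (0.95 ± 0.28, adjusted p = 0.0953) did not pass. Each of these 4 lists had an adjusted p = 0.813 with an estimated correlation. Fry, which tests a list's own direction, called the B cell and the lymphoid priming lists.

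Single genes also changed in lists that did not pass as a whole. In the granulocyte list 4 of 26 members rose (5 rose and 2 fell adjusted over the list alone), among them the leukotriene receptor Ltb4r1 (1.21 ± 0.18) and the neutrophil elastase gene Elane (1.91 ± 0.39). Elane lost its call without mouse 1, 4, 5 or 6 (1.45 to 2.36, adjusted p up to 0.117), and with the compared groups alone or the Kdm5d signal as a covariate. Of the p53 targets 3 of 26 rose (3 rose and 1 fell adjusted over the list alone), including the cell cycle inhibitor Cdkn1a (1.81 ± 0.29) and Perp (1.48 ± 0.20). In the megakaryocyte list 4 of 23 fell and 1 rose (5 and 1 adjusted over the list alone), with Mmrn1 at -2.43 ± 0.33. The angiopoietin receptor Tek fell by 1.73 ± 0.19, while the basement membrane collagens Col4a1 and Col4a2 rose by 1.64 ± 0.27 and 1.80 ± 0.22. The stress-induced genes Chac1 and Trib3 rose by 1.67 ± 0.21 and 1.59 ± 0.27, and the chemokine Ccl9 by 2.11 ± 0.21. Without both mice with a Kdm5d signal, 36 of the 58 named genes called in LSK cells kept their calls. Of those described here, Col4a1 (1.63, adjusted p = 0.0939), Elane (1.45, 0.186), Mpeg1 (-1.33, 0.0797) and Irgm2 (-1.34, 0.0538) did not.

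In KO myeloid progenitors the 3 largest decreases were again in Vpreb3, Igll1 and Vpreb1. Vpreb3 changed by -4.78 ± 0.26, Igll1 by -3.28 ± 0.31 (9.74-fold) and Vpreb1 by -3.11 ± 0.37 (8.61-fold, SE, n = 2 mice per group). The actin-severing protein Scin fell by 2.79 ± 0.22, the beta-glucan receptor Clec7a by 2.48 ± 0.30, Mboat2 by 2.45 ± 0.21, the heparanase gene Hpse by 2.44 ± 0.21, the protease Ctse by 2.39 ± 0.25, and the protease inhibitor Slpi by 2.38 ± 0.26. Aldh1a7 changed by -2.37 ± 0.30.

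The sialomucin gene Podxl rose most in KO myeloid progenitors, by 4.42 ± 0.41 (21.4-fold, adjusted p = 0.000976), followed by Ptprf at 3.39 ± 0.24 (10.5-fold). The p53 target Zmat3 rose by 2.76 ± 0.29, the RNA-binding protein Celf4 by 2.70 ± 0.21, the cysteine synthesis enzyme Cth by 2.56 ± 0.27, the pseudokinase Trib3 by 2.49 ± 0.27, Parm1 by 2.39 ± 0.26, Smim6 (1110017F19RIK on the array) by 2.32 ± 0.21 and Arhgap45 (HMHA1 on the array) by 2.31 ± 0.21. The erythroblast hormone Erfe (FAM132B on the array) rose by 2.26 ± 0.34. Of these 20 genes, Erfe alone lost its call in fits without 1 mouse (without mouse 5, 6 or 8, at 1.96 to 2.55, adjusted p up to 0.134), and it also lost it with the Kdm5d signal as a covariate. Arhgap45 in myeloid progenitors lost its call with all arrays in the fit and the mouse as a random block (adjusted p = 0.682).

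Limma called 469 of 17741 genes in myeloid progenitors, 161 higher and 308 lower in KO, of which 117 and 199 differed by at least 2-fold. The count was 291 without mouse 5, 247 without mouse 6 and 196 without mouse 8, and without mouse 7 it was 325 with more genes higher (195) than lower (130). Without both mice with a Kdm5d signal it was 244 (66 higher, 178 lower).

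In myeloid progenitors 6 lists passed camera. Of the p53 targets 6 of 26 rose and 0 fell (7 rose adjusted over the list alone), with a median of 0.33 (adjusted p = 0.295 with an estimated correlation), including Zmat3, Perp (1.96 ± 0.20) and Phlda3 (1.41 ± 0.16). The cell cycle inhibitor Cdkn1a rose by 1.45 ± 0.29 and lost its call without mouse 5, 6, 7 or 8 (1.17 to 1.73, adjusted p up to 0.188). In the B cell list 6 of 15 fell and 0 rose (7 fell adjusted over the list alone; median -0.43, adjusted p = 0.112 with an estimated correlation), with Ebf1 at -1.64 ± 0.14. In the interferon response list 9 of 38 fell and 0 rose (22 fell adjusted over the list alone; median -0.79, adjusted p = 0.380 with an estimated correlation). Isg15 fell by 2.20 ± 0.35 and the interferon-induced GTPase gene Igtp by 1.83 ± 0.27. Isg15 lost its call without mouse 7 or 8 (adjusted p up to 0.0964, -2.85 to -1.55 over the fits without 1 mouse) and Igtp without mouse 8 (adjusted p = 0.0563, -2.17 to -1.48). Isg15 also lost it with the compared groups alone, and Cdkn1a with the Kdm5d signal as a covariate.

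The monocyte and macrophage list shifted down in KO myeloid progenitors with 4 of 21 members lower (8 fell and 2 rose adjusted over the list alone; median -0.42, adjusted p = 0.295 with an estimated correlation). Its perforin-like member Mpeg1 (-1.26 ± 0.23) lost the call without mouse 5, 6 or 8 (-1.54 to -0.99, adjusted p up to 0.206). In the lymphoid priming list 3 of 14 fell (5 adjusted over the list alone; median -0.18, adjusted p = 0.553 with an estimated correlation), with Rag1 at -2.32 ± 0.24, and the list did not pass without mouse 5 (median -0.13, adjusted p = 0.109), without both mice with a Kdm5d signal (-0.13, adjusted p = 0.0857) or with that signal as a covariate (-0.07, adjusted p = 0.162). The amino acid synthesis and one-carbon list shifted up with 0 of 15 members past the threshold (0 adjusted over the list alone; median 0.39, adjusted p = 0.724 with an estimated correlation) and did not pass without mouse 5 (0.25, adjusted p = 0.126) or mouse 8 (0.30, adjusted p = 0.144). This list also did not pass without both mice with a Kdm5d signal (0.25, adjusted p = 0.110), with that signal as a covariate (0.26, adjusted p = 0.121) or among probes above the 50th percentile (0.39, adjusted p = 0.0631). Slc7a5 (0.77 ± 0.32) and Asns (0.74 ± 0.49) did not pass. Fry called the B cell list and the p53 targets.

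Other lists changed in single members. In the cytokine signalling list 3 of 24 members rose and 1 fell (3 and 2 adjusted over the list alone), against 4 and 1 in LSK cells (6 and 2). The members that rose in myeloid progenitors were the feedback inhibitors Socs3 (2.18 ± 0.32), Socs2 (2.10 ± 0.30) and Cish (1.99 ± 0.32). These lost their calls in some fits without 1 mouse, Socs3 without mouse 6 (adjusted p = 0.0566), Socs2 without mouse 5 (0.0502) and Cish without mouse 5, 6 or 8 (up to 0.0965), at 1.53 to 2.47 over all these fits. Gzmb fell by 1.87 ± 0.21 and Tcf7 rose by 1.60 ± 0.16. Prss34 fell by 1.73 ± 0.19 and Mcpt8 rose by 1.46 ± 0.18, and Chac1 rose by 1.66 ± 0.21. In the megakaryocyte list, of which 1 member rose and 4 fell in LSK cells, 4 of 23 rose and 1 fell in myeloid progenitors (7 and 3 adjusted over the list alone), and 0 members passed the test of the difference between the populations. Those that rose included the P-selectin gene Selp (1.83 ± 0.33), which lost its call without mouse 5, 6 or 7 (adjusted p up to 0.127), and the platelet glycoprotein gene Gp5 (2.84-fold), which lost it without mouse 8 (adjusted p = 0.0828), while Mmrn1 (-0.97, adjusted p = 0.279) did not pass, with a mean under 6.5 in KO mice. In the dendritic cell list 3 of 16 fell (4 adjusted over the list alone), with a median of 0.03 and a mean of -0.23, and in the granulocyte list 1 of 26 rose (1 adjusted over the list alone).

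Without both mice with a Kdm5d signal, 38 of the 57 named genes called in myeloid progenitors kept their calls. Of those described here, Erfe (2.11, adjusted p = 0.166), Cdkn1a (1.17, 0.173), Mpeg1 (-1.33, 0.0944), Socs2 (1.85, 0.0845) and Cish (1.86, 0.0710) did not.

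**Figure D2:**
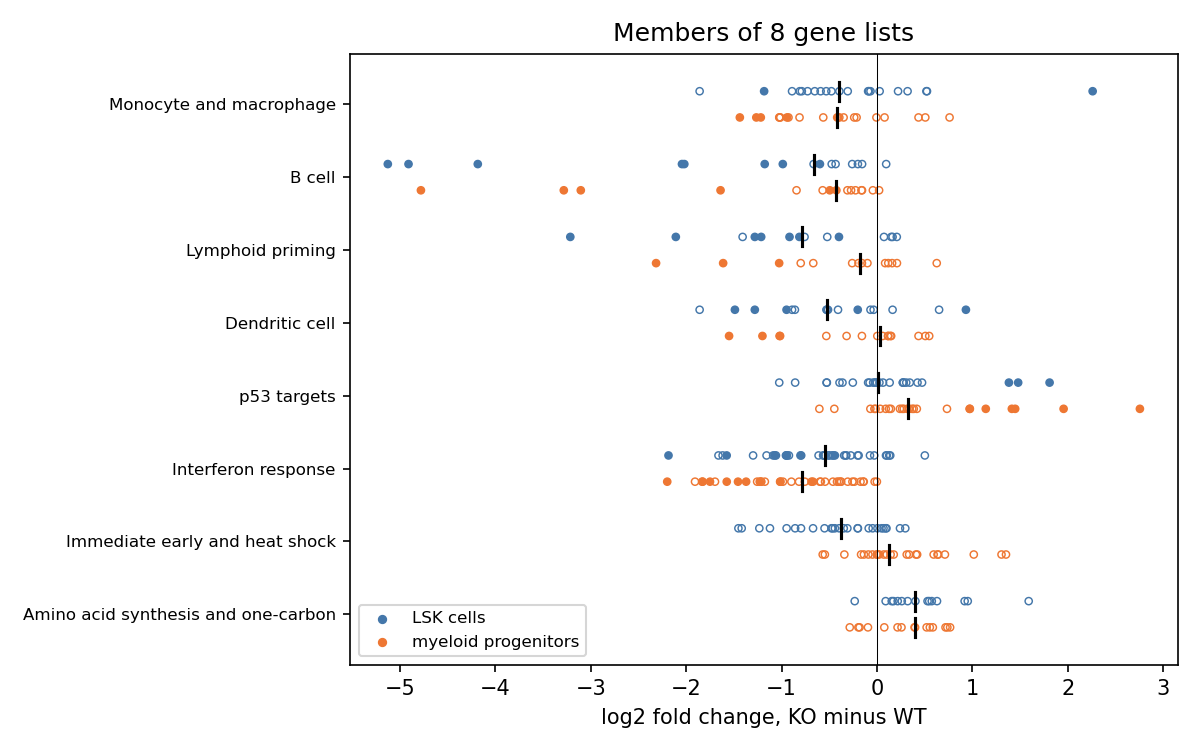
Log2 fold change (KO minus WT) of the measured members of the 8 gene lists that passed camera in LSK cells (blue) or myeloid progenitors (orange). Filled points passed the threshold, open points did not, and black bars are list medians, for the B cell list -0.66 in LSK cells and -0.43 in myeloid progenitors.

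Across both populations, the genes changed most were Podxl (3.22 ± 0.29), Ptprf (2.89 ± 0.17), Tcp11x2 (2.54 ± 0.15), Sulf2 (2.28 ± 0.14) and Celf4 (2.10 ± 0.15) on the high side. On the low side were Vpreb3 (-4.96 ± 0.19), Igll1 (-4.10 ± 0.22), Vpreb1 (-3.65 ± 0.26), Rag1 (-2.77 ± 0.17) and Apol11b (-2.38 ± 0.31). Each of these 10 kept its call whichever mouse was left out. The mean of both contrasts called 1410 genes, 549 higher and 861 lower in KO. The count was 794 without mouse 8 and 736 without both mice with a Kdm5d signal.

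Of the lists, 9 passed camera for the mean of both contrasts. In the interferon response list 19 of 38 members fell and 0 rose (25 fell adjusted over the list alone; median -0.60, adjusted p = 0.457 with an estimated correlation), and in the B cell list 9 of 15 fell and 0 rose (12 fell adjusted over the list alone; median -0.70, adjusted p = 0.0641 with an estimated correlation). Of the p53 targets 6 of 26 rose and 0 fell (6 and 1 adjusted over the list alone; median 0.17, adjusted p = 0.622 with an estimated correlation). In the amino acid synthesis and one-carbon list 1 of 15 rose (8 adjusted over the list alone; median 0.42, adjusted p = 0.748 with an estimated correlation).

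In the monocyte and macrophage list 6 of 21 members fell and 1 rose on average (11 and 1 adjusted over the list alone, median -0.41), and in the lymphoid priming list 8 of 14 fell (9 adjusted over the list alone, median -0.42). With an estimated correlation the adjusted p was 0.439 for both. In the dendritic cell list 6 of 16 fell (7 fell and 1 rose adjusted over the list alone, median -0.30), and in the granulocyte list 3 of 26 rose (5 adjusted over the list alone, median 0.21). In the ribosome biogenesis and Myc list 0 of 19 passed (0 adjusted over the list alone, median 0.26). These 3 had an adjusted p of 0.748 with an estimated correlation, so that 0 of the 9 lists passed that way.

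The changes in the populations, which shared no mice, were set against each other gene by gene. Across 17741 genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.548 and Spearman rho = 0.388, and 60.1% of the genes had the same sign in both. The genes higher in both numbered 67, against 2.80 for independent lists, and those lower in both 165, against 8.94. Called in opposite directions were 0 genes, against 5.36 and 4.67 for independent lists. Both contrasts used the same estimate of each gene's spread, so the calls were not independent and these expected numbers are only a rough reference. In each population a WT mouse and no KO mouse had a Kdm5d signal, so a difference tied to that signal would enter both contrasts alike. Without those mice Pearson r was 0.478, and the shared calls were not counted. Of the 824 genes called in LSK cells, 763 had the same sign in myeloid progenitors, and of the 469 called there, 445 had the same sign in LSK cells.

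**Figure D3:**
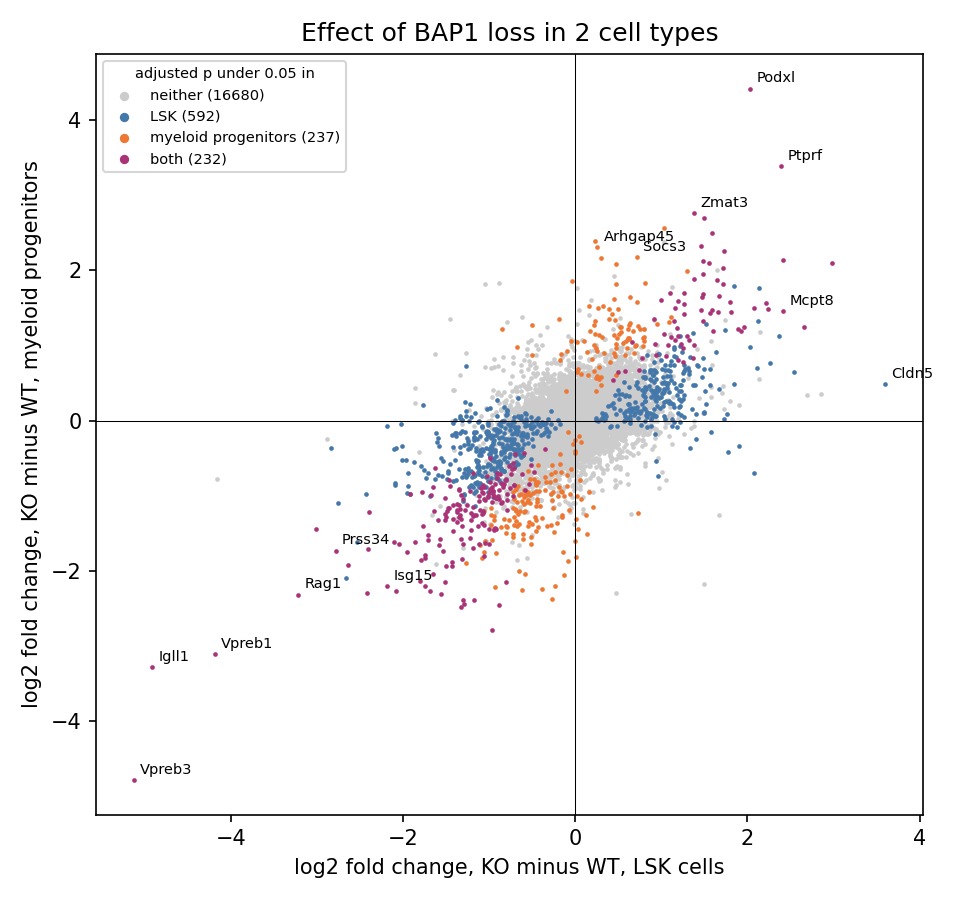
Log2 fold change (KO minus WT) of each of 17741 genes in LSK cells (x axis) and in myeloid progenitors (y axis), coloured by where the gene passed the threshold. The 232 genes called in both lie in the same direction in both, with Vpreb3, Igll1 and Vpreb1 at the low end and Podxl and Ptprf at the high end.

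The test of the difference between the effects called 11 genes, 3 with a higher and 8 with a lower signed log2 effect in LSK cells. Cldn5 rose in LSK cells and changed by 0.48 in myeloid progenitors (difference 3.12 ± 0.34, adjusted p = 0.0124), and Fastk changed by 2.08 against -0.70 (difference 2.78 ± 0.32, adjusted p = 0.0137). Both kept this call whichever mouse was left out. Among the genes with a lower signed effect, Slc35d3 and Paqr5 changed by -2.19 and -2.11 in LSK cells against -0.07 and -0.37 in myeloid progenitors. Arhgap45, Fgf13 and the kinase gene Pim1 changed by 0.26, -0.51 and -0.19 in LSK cells against 2.31, 1.27 and 1.36 in myeloid progenitors. The differences were -2.12 ± 0.26 for Slc35d3, -2.05 ± 0.29 for Arhgap45, -1.78 ± 0.23 for Fgf13, -1.74 ± 0.23 for Paqr5 and -1.55 ± 0.23 for Pim1. Each of these 5 lost the call without mouse 6, Slc35d3, Paqr5, Arhgap45 and Pim1 also without mouse 8, Arhgap45 and Pim1 without mouse 1, Arhgap45 without mouse 5 and Pim1 without mouse 7 (adjusted p up to 0.129). Without both mice with a Kdm5d signal Arhgap45 (adjusted p = 0.147) and Pim1 (0.0979) lost it, and Arhgap45 in the difference also with the mouse as a random block (adjusted p = 0.928). Next by unadjusted p, and not past the threshold, were Pdzph1 (1.83, adjusted p = 0.0700), Gzmb (1.79, 0.0784) and Tmprss4 (1.21, 0.0889). Paqr5 in myeloid progenitors of both genotypes, Pdzph1 in LSK cells of both genotypes and Fgf13 in KO LSK cells had means under 6.5, near the low end of the arrays. With eBayes without trend and robust options limma called 0 genes, and fits without 1 mouse called 10 (mouse 6, with 0 lower) to 117 (mouse 4). They called 45 without mouse 1, 55 without mouse 2, 80 without mouse 3, 35 without mouse 5, 57 without mouse 7 and 13 without mouse 8. At an unadjusted p under 0.05 the fit with all mice held 1367 probes.

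The comparison of the WT populations checks the labels of the sort. In the stem cell list 18 of 26 members were higher in LSK cells and 0 lower (23 and 0 adjusted over the list alone; median 1.38, adjusted p = 0.214 with an estimated correlation). In the erythroid list 11 of 29 were lower and 1 higher (16 and 3 adjusted over the list alone; median -1.02, adjusted p = 0.401 with an estimated correlation). Elane (-4.33 ± 0.39), Anxa3 (-3.26 ± 0.40), Atp1b2 (-3.15 ± 0.68), the carbonic anhydrase gene Car1 (-3.12 ± 0.55) and Cldn15 (-3.09 ± 0.40) were lower in LSK cells. The immunoglobulin joining chain gene Jchain (IGJ on the array) was higher by 6.03 ± 0.95, the immediate early genes Fosb, Fos and Nr4a1 by 5.96 ± 1.13, 4.92 ± 0.83 and 4.84 ± 0.74, and the chemokine gene Ccl4 by 4.36 ± 0.62. Over the immediate early and heat shock list 14 of 26 were higher and 1 lower (16 and 2 adjusted over the list alone; median 1.76, adjusted p = 0.375 with an estimated correlation).

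Limma called 2403 genes in this comparison, 1434 higher and 969 lower in LSK cells, with 1075 without mouse 1, 1437 without mouse 5 and 618 without both. Ccl4, Elane, Anxa3 and Cldn15 kept their calls whichever mouse was left out, while Jchain, Fosb, Fos, Nr4a1, Atp1b2 and Car1 lost theirs in at least 1 such fit (adjusted p up to 0.198). Without both mice 1 and 5 Jchain (adjusted p = 0.243), Fosb (0.296) and Fos (0.202) did not pass, nor did Fosb with the Kdm5d signal as a covariate. In WT myeloid progenitors Fosb had a mean of 6.38 and Jchain read 5.98 in mouse 6, near the low end of the arrays. The populations came from different mice, so the test set them against the spread between mice. Camera called 20 of the 33 lists, and 0 with an estimated correlation.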

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

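The tests below that exchange the labels of 2 single mice, or use the ratio of linear drops or the Bap1 probe, were chosen after the values were seen, as was the removal of the mice with a Kdm5d signal. The fits without 1 mouse and the count over the other splits of the mice were chosen before. Groups of 2 mice are too small for a test of outlying mice.

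The effect of the KO differed between the populations, by the test of the difference, for 11 genes. The difference (LSK effect minus myeloid progenitor effect, log2) was 3.12 for Cldn5, 2.78 for Fastk, 0.57 for Afm, -0.82 for C430049B03Rik, -0.88 for Asb4, -1.40 for Abcg3, -1.55 for Pim1, -1.74 for Paqr5, -1.78 for Fgf13, -2.05 for Arhgap45 and -2.12 for Slc35d3. Afm, C430049B03Rik, Asb4 and Abcg3 were named here because they passed this test, after their values were seen. Pim1, Fgf13 and Arhgap45 passed in myeloid progenitors and not in LSK cells, the other 8 in LSK cells and not in myeloid progenitors. Afm, C430049B03Rik, Asb4, Abcg3 and Paqr5 had means under 6.5, near the low end of the arrays, in myeloid progenitors of both genotypes, as did Fgf13, Asb4 and C430049B03Rik in KO LSK cells and Afm in WT LSK cells.

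Camera on the same difference called 7 lists, each with a lower signed log2 effect in LSK cells, which need not be a weaker one. The B cell and lymphoid priming lists fell further in LSK cells (medians -0.66 and -0.79) than in myeloid progenitors (-0.43 and -0.18). The p53 targets had medians of 0.01 and 0.33. The other lists had a negative median in LSK cells and a positive one in myeloid progenitors. The medians of the difference were -0.21 for the stem cell list, -0.21 for the megakaryocyte list, -0.28 for the B cell list, -0.46 for the lymphoid priming list, -0.25 for the G2 and M phase list, -0.28 for the p53 targets and -0.37 for the immediate early and heat shock list. With an estimated correlation 0 of them passed (adjusted p = 0.314 to 0.980). The list tests of the difference were not rerun with mice left out. In LSK cells the median of the immediate early and heat shock list was 0.00267 without mouse 1.

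The fall of the B cell list in both KO populations was weighed against the sex of the mice and against the cells in the sort. Without the 2 mice with a Kdm5d signal its median stayed at -0.77 in LSK cells and -0.46 in myeloid progenitors, past camera at the preset correlation of 0.01. The fall was thus also seen among the mice without this signal. That fit left a single WT mouse per population, in myeloid progenitors mouse 6, with Xist at 7.51 against 7.80 to 7.87 in KO mice. It therefore cannot tell the genotype from the sex of the mice or from a single WT mouse. With all mice and an estimated correlation the list did not pass (adjusted p = 0.0683 and 0.112). A B-lineage source with a fixed profile, smaller in the KO sorts, would give every such gene the same ratio of linear drops between the sorts. For the 9 genes of the B cell and lymphoid priming lists that fell in both, of which Vpreb1 was the brightest (9076 to 499 on the linear scale in LSK cells), the highest (Il7r) and lowest (Ms4a1) log2 ratios differed by 1.85 standard errors, where the same fold change of each gene within the cells of both sorts would have given 2.30. A smaller share of B-lineage cells, which the lineage-negative gate is meant to remove once mature, and lower transcription within progenitors therefore cannot be told apart here, since only ratios apart by more than 1.45 on the log2 scale would have passed the bound of 3 standard errors.

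The fall of the interferon response list was weighed against the sex of the mice and against a single mouse that sets the shift. Without the 2 mice with a Kdm5d signal its median was -0.44 in LSK cells and -1.03 in myeloid progenitors, past camera at the preset correlation of 0.01. It passed likewise in the cell type of the mouse left out in 8 of 8 fits (medians -1.03 to -0.40). With all mice it did not pass camera at an estimated correlation (adjusted p = 0.813 and 0.380) or directional fry (adjusted p = 0.240 and 0.0855). The estimated correlation was 0.398, so a pass at the preset correlation is weak evidence. The medians stayed negative whichever mouse was left out, so no single mouse set their direction. The sex of the mice stays open, since a single WT mouse per population was left without those 2 mice. The genotype itself, and any difference in the housing or infection of the mice, which the labels do not give, stay open as untested.

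The Bap1 probe, higher by 0.30 on average in KO mice and not past the threshold, was weighed against exchanged labels and against the place of the probe. Exchanging 1 KO and 1 WT mouse of a population, in each of the 8 possible ways, left at most 2 genes called on average over both populations, against 1410 by the labels, so an exchange of labels between 2 single mice of a population is argued against, while an exchange of all labels is not. Whether the probe lies outside the deleted part cannot be told apart from a transcript that persists, since the probe's place in the gene is not given in the sources used here.

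The number of genes changed on average over both populations was set against other splits of the mice with 2 of 4 mice per population in each arm. Of the 18 splits, 1 called as many as the real 1410 genes, the real split itself, and the highest of the others called 11. With 18 splits the share cannot fall under 0.05.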

How the results depend on the processing

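The fits without the 2 mice with a Kdm5d signal and with that signal as a covariate were chosen after seeing the data. Of the named genes, 155 calls, each of a gene in a comparison, were followed, and 0 reversed under up to 15 settings. These settings left out the percentile filters, the eBayes options, other thresholds, independent arrays and averaged probes. A gene whose KO mice both lay on one side of both WT mice could not reverse when mice were left out. The random and replicate blocks left the fold changes as they were, so 0 reversals was largely fixed in advance. Fits with the compared groups alone covered the 115 calls in LSK cells and myeloid progenitors, and 15 of these were lost. Repeated quantile normalization and median centring kept all 155 calls. This too was largely fixed in advance, since the deposited arrays already shared nearly the same distribution. The replicate block and the random block kept 153 each (both lost Arhgap45 in myeloid progenitors and in the difference), and fits without 1 mouse between 119 and 142. After subtraction of each mouse's mean, same-numbered arrays of different mice correlated at -0.00167 on average (-0.250 to 0.277 over pairs). Differently numbered ones correlated at 0.000817 on average. The array numbers thus did not pair arrays on average, though single pairs were not tested. The causes of the changes below were not tested unless stated.

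The counts below are of genes in LSK cells (824), myeloid progenitors (469), the average (1410), the difference (11) and the WT populations (2403), in that order. With the mouse as a random block they were 2671, 1629, 3196, 454 and 4675, and with the replicate block added 2570, 1549, 3120, 402 and 4543. With every array as an independent sample, which counts arrays of the same mouse as replicates, they were 4788, 3142, 5189, 1837 and 7098. Without the 2 mice with a Kdm5d signal, a fit with fewer mice, they were 330, 244, 736, 50 and 618. With the Kdm5d signal as a covariate LSK cells had 535 and the average 851. With the compared groups alone LSK cells had 481. EBayes without trend and robust options gave 549 in LSK cells, 288 in myeloid progenitors and 0 for the difference, and an adjusted p under 0.1 gave 1275 in LSK cells and 26 for the difference. Probes above the 50th percentile gave 31 for the difference. Fits without 1 mouse ranged from 428 to 969, 196 to 546, 794 to 1477, 10 to 117 and 1075 to 2748.

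Of the gene lists, 7 passed in LSK cells and 6 in myeloid progenitors, and lists were rerun for these contrasts alone. With an estimated correlation 0 and 0 passed, with fry 2 and 2, and with the mixed test of fry 25 and 22. In LSK cells 4 passed among probes above the 50th percentile, 11 without the 2 mice with a Kdm5d signal, and 5 to 13 in fits without 1 mouse (6 to 9 in myeloid progenitors). The median of the immediate early and heat shock list in LSK cells turned to 0.00267 without the 2 mice with a Kdm5d signal and without mouse 1, and ranged from -0.73 to 0.00267 over fits without 1 mouse. Over all 20 settings run for lists, the median of the B cell list ranged from -2.42 to -0.56 in LSK cells. In myeloid progenitors it ranged from -1.97 to -0.42. These settings include the percentile filters, which drop dim members of a list, so the medians do not all cover the same genes. The correlation of the effects, 0.548, was 0.478 without the 2 mice with a Kdm5d signal and 0.423 to 0.593 in fits without 1 mouse. Signal over background could not be assessed from these values.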

Other observations

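The genes below were put together after their values were seen, and they were not tested as a list. Col4a1, Col4a2 and Perp had also been named in the Results, Perp as a member of the tested p53 targets. On average over both populations (log2 change, SE), the collagen genes Col4a1, Col4a2 and Col18a1 rose in KO mice by 1.76 ± 0.19, 1.69 ± 0.16 and 1.87 ± 0.16, and the laminin gene Lama5 by 1.28 ± 0.15. The matrix metalloproteinase genes Mmp14 and Mmp17 rose by 1.78 ± 0.19 and 1.56 ± 0.14, the adhesion molecule gene Epcam by 1.72 ± 0.27, the envoplakin gene Evpl by 1.88 ± 0.14 and the p53 target Perp by 1.72 ± 0.14. The small GTPase gene Arl3 fell by 1.83 ± 0.15, the intraflagellar transport gene Ift81 by 1.36 ± 0.17, and the BBSome genes Bbs7 and Bbs1 by 1.32 ± 0.14 and 1.29 ± 0.12.

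Of these 13 genes, Lama5 (0.92, adjusted p = 0.0567) and Epcam (1.33, adjusted p = 0.155) did not pass in myeloid progenitors, and the others passed in each population. Each kept its average call whichever mouse was left out. Epcam alone lost that call without both mice with a Kdm5d signal (adjusted p = 0.0813) and with the signal as a covariate. In myeloid progenitors alone, Col4a1 (1.93) and Col4a2 (1.45) lost their calls without both mice with a Kdm5d signal. Col4a2 also lost it without mouse 8, while Perp kept its call in all these fits. In WT myeloid progenitors Epcam (mean 6.12) and Lama5 (mean 6.31), and in KO myeloid progenitors Bbs1 (6.10 and 6.11 in the mice), lay near the low end of the arrays.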
